A study of Mus musculus with 40 samples.

How the data were processed

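The series table held 40 columns, and each column was mapped to 1 brain through its labels. Per the labels, adult female C57BL/6 mice received live Listeria monocytogenes strain EGD or sterile phosphate-buffered saline (PBS) by vein. They were bled and perfused before the brain was taken, and the brain was split lengthwise, with 1 part frozen for RNA. Labelled RNA was hybridised to Clontech plastic arrays that carry each probe as a pair of spots. The isotope was 33P in the sample labels and 32P in the design text, a difference left open here. Infected animals were chosen for similar bacterial counts in spleen on day 1, blood on day 2 and brain on days 3 and 4, and control brains were assigned to them at random.

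Per the labels and the design text, the authors subtracted background in ArrayVision, averaged both spots of a probe, divided each array by its median and then divided each probe by the median of uninfected samples in Genespring GX 7.3. The deposited values were a linear ratio of each array to the PBS median of the same probe on the same day, since that median was exactly 1 for all 5030 probes on each of the 4 days. Of 201200 values, 11649 were exactly 0.01 and 6 lay under it. Because each day had its own PBS reference, levels could not be compared between days, and only differences between infected and PBS brains were.

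The design fixed before the data were examined had assumed values relative to the array median. It planned division by the median over all probes, a floor, a filter on dim probes and an intensity trend in the variance. On ratios that filter would have removed no probe, so the scale, the floor, the filter and the fit without a trend were set after the values had been examined. Results of the fit as first written are given where they changed which probes or lists passed on a day.

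Undetected spots of an array shared a lowest level. In the ratio of any 2 arrays of a day, probes undetected on both therefore gave 1 common value. The most frequent ratio of each array pair, over values above 0.05, gave the lowest level of each array on the deposited scale. Lower limits of 0.025 and 0.0125 were provided for where pairs differed by over 0.02 (log2). In the real data pairs differed by at most 0.0048, and only the limit of 0.05 was used. A probe's lowest level counted as recovered where at least 3 arrays shared its lowest value within 0.03 (log2, more where rounding was coarse), or 2 arrays with a gap of at least 1 to the next. Values at 0.01 or less were also treated as undetected. The share of values at the lowest level was 21.0%, 40.5%, 72.9% and 78.7% on days 1 to 4.

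The noise floor of a day was the median level of probes seen above the lowest level on at most 2 arrays. It lay at 122, 76.8, 127 and 474 times the lowest level. Probes with a recovered lowest level were floored there and are given as log2 over the lowest level. The others are given as log2 ratio to the PBS median and were floored at 0.2 of it, so that a level under that share of the median could not be measured for them, while a rise had no such limit. Arrays were scaled within a day over the probes above the lowest level on every array, which numbered 1605, 1321, 190 and 69. Where values at the floor lie in 1 group alone, a difference is a lower limit to its size, and where both groups hold such values its size depends on the floor. A probe was tested on a day when at least 4 arrays lay above its floor, whatever their group.

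Arrays of a day were compared in pairs before any test. On day 3, PBS replicates 12 and 13 lay within 1% of each other for 95.0% of the 805 probes detected on both, and infected replicates 13 and 14 did so for 72.8% of theirs. Over the other 178 pairs the highest share was 8.39%. Each of those 2 pairs was averaged and counted as 1 replicate, which left 4 against 4 on day 3 and 5 against 5 on the other days. PBS replicate 8 of day 2 names day 1 in its title, PBS replicate 15 of day 3 names day 2 in its source, and 2 PBS arrays of day 1 carry mouse number 1 and are called 1a and 1b here. All were kept in the group that their remaining labels give. Apart from the PBS arrays 1a and 1b, which by their number may come from 1 animal, replicates are separate animals per the labels. The number of arrays limits the precision of every value.

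Infected and PBS brains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 model with a mean and an infection effect per day. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Differences of the infection effect between days were tested as contrasts in limma. Gene lists, 22 in number and fixed before the data were examined, were tested with limma's camera (preset correlation 0.01, at least 5 members tested, 1 probe per gene), again with an estimated correlation, and with fry. The list tests used the arrays of each day and, for genes with several probes, the probe above its floor on most arrays, where the fixed design had named all arrays and the probe of highest mean. The Mann-Whitney test of the design text was run as an exact two-sided test. Its smallest p was 0.0079 with 5 against 5 replicates and 0.029 with 4 against 4, the lowest that these numbers allow. Only a very large number of probes at that p could pass adjustment. A count of 0 after adjustment in that test was therefore nearly fixed by the number of replicates on every day. Fold changes are log2, infected over PBS, with limma's standard error, and levels are means with SD.

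Genes were named by a rule fixed beforehand. It takes the 8 largest rises and 8 largest falls among probes past the threshold that have 1 gene and moved the same way in every infected brain, and, where under 4 passed, the 4 smallest p besides. It adds up to 4 members of each discussed list by p, the 5 smallest p of each contrast between days, and 15 inflammatory genes regardless of result, of which 10 were on the array. Of these, Tnf and Irf7 had too few arrays above the floor to be tested on any day. Ccl2 and S100a8 were tested on day 1 alone, Isg15 on day 2 alone, Il1b and Icam1 on days 1 and 2, and Ccl5 on days 1 to 3. Only Cxcl9 and Irf1 were tested on every day. Which lists to discuss was decided after the list results were seen: those with an unadjusted p under 0.05 on a day, and the interferon list on every day. Probes E09c7/d7 and K06a3/b3, which have no gene in the probe table, were named after their values were seen. That table pairs 4633 probes with 1 gene and 5 with several, and 392 are unnamed here. Identifiers of 4624 probes matched the reference gene table (GRCm38.p6), and 0 symbols differed. No coordinates are given, because no genome build is named for the probes.

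Same-numbered infected and PBS brains of day 3 deviated together, with correlations of 0.30, 0.20 and 0.18, and each correlated best with its own number. Since control brains were assigned at random, whether the numbers pair the samples of that day was left open. On each other day at least 1 same-numbered pair did not deviate together (lowest correlations -0.38, 0.01 and -0.10 on days 1, 2 and 4). The highest there were 0.41, 0.18 and 0.09, and the numbers were not taken to pair the samples. Reported results come from fits without a block on every day, and those with the mouse number as a block are given as an alternative. The fits with a block also leave out every brain whose number occurs in only 1 group of its day. Their results can therefore differ through the block or through the brains left out.

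The steps were tested on 5030 simulated probes per day, 50 of them changed at each of 4 sizes, passed through the authors' divisions. Of the simulated values, 98.1%, 98.1%, 98.9% and 99.1% were correctly told apart as detected or undetected on days 1 to 4. The recovery step had been revised after the first simulation of day 2, where 68.0% were. The revision left the real values as they were. With a spread between arrays close to that of the real probes, 58.5%, 60.0%, 56.3% and 37.5% of tested probes with a log2 change of 4 were called on days 1 to 4, and 14.3%, 11.4%, 0% and 12.5% of those with a change of 2. Of unchanged probes, 3, 2, 0 and 0 were called. Those simulated arrays had more probes detected on every array than the real ones, 536 against 69 on day 4, and overstate the power. A wider spread was chosen from 5 pairs of settings because it came close to the real counts (64.5 on day 4). With it 0% of probes with a change of 4 were called on any day, so a count of 0 does not show that nothing changed. A list of 15 raised probes had a camera p of at most 9.1e-07 on every simulated day with either spread. Its members were raised by log2 changes of 2 to 5 and varied independently, so smaller changes and correlated lists were not covered.

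Alternatives covered quantile normalization, lower and higher floors, no filter and a stricter one, array weights, arrays with doubtful labels, the mouse number as a block, the arrays of a day alone, other scalings, a variance trend, array clusters, and each replicate left out. Pooling the PBS arrays of all days, cyclic loess and a test among the PBS groups were planned and not run, because levels of different days share no reference. The recovery, tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.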

Results

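Gene expression was measured on 40 arrays of mouse brain, 5 of animals infected with Listeria monocytogenes and 5 of animals given PBS on each of days 1 to 4 after injection. On day 3, near-identical arrays were counted once, which left 4 replicates in each group. The question of the series was how the brain transcriptome changes during a lethal infection. The number of probes above the lowest level ranged from 3489 to 4651 per array on day 1, from 2374 to 4490 on day 2, from 789 to 1987 on day 3 and from 513 to 2073 on day 4. Probes tested numbered 3633, 2649, 797 and 647. Chance alone would give 181.65, 132.45, 39.85 and 32.35 of these at an unadjusted p under 0.05, the background for the unadjusted counts below.

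**Figure D1:**
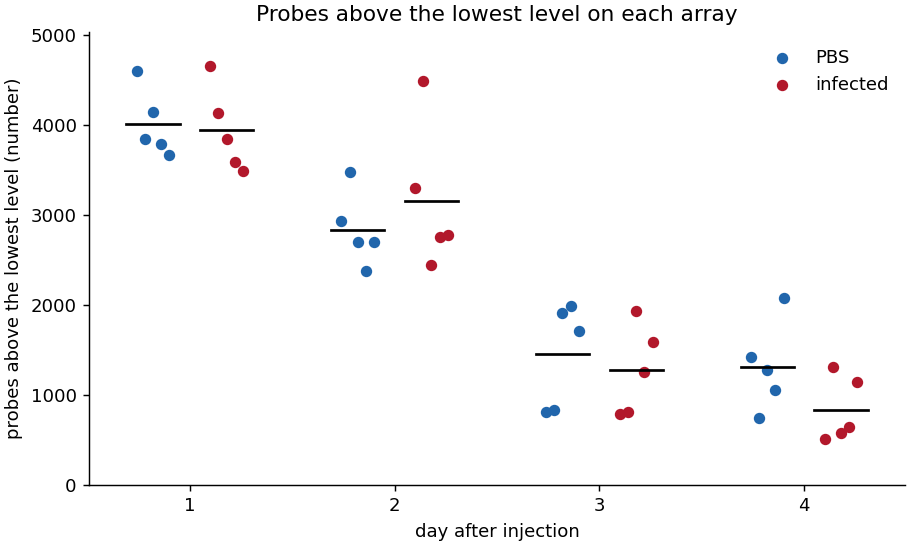
Number of probes above the lowest level on each array (y axis) by day (x axis), PBS in blue and infected in red. Counts lay between 3489 and 4651 on day 1 and between 513 and 2073 on day 4.

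On day 1, genes of the mitochondrial respiratory chain, which carries out oxidative phosphorylation, rose as a group in infected brains. Of 14 members tested, 12 had a higher mean, and the median log2 fold change was 0.42 against -0.22 for the other tested genes (camera adjusted p = 0.0322). Adjusted p was 0.921 with an estimated correlation, and 0.540 in fry, which asks whether the genes of a list move 1 way without comparing them with other genes. The members of smallest p encode subunits of ATP synthase and cytochrome oxidase: Atp5k at 2.57 ± 0.96 (SE, n = 5 and 5), Atp5b at 1.04 ± 0.59, Atp5a1 at 0.57 ± 0.60 and Cox7a2 at 0.68 ± 0.88. Atp5b was at 0.49 without PBS replicate 1a, Atp5a1 at 0.31 without PBS 4 and Cox7a2 at 0.096 without PBS 3 or 4. None of these passed by itself, and 0 members passed when adjusted over the list alone. Of 100 splits of the day 1 arrays, the real one included, 51 gave as many lists, so chance cannot be excluded for this call.

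No gene passed by itself on day 1. limma called 0 of 3633 probes, with 158 at an unadjusted p under 0.05, of which 19 were higher and 139 lower. The exact Mann-Whitney test on the deposited scale gave 207 probes at that level and 0 after adjustment, a count that the number of replicates nearly fixed. Of the 207, 159 had a 2-fold difference, 120 higher and 39 lower, the opposite majority to that of limma on scaled levels. The smallest p belonged to Ppm1d, a protein phosphatase, at -2.63 ± 0.64, Sh2d1b1, a signalling adaptor of natural killer cells, at -2.84 ± 0.70, Mr1, an antigen-presenting molecule, at -2.85 ± 0.75, and Pglyrp1, which binds bacterial peptidoglycan, at -2.68 ± 0.72. Their adjusted p was 1.00, but with no filter 8 probes passed, all lower, among them Sh2d1b1 (0.00947), Ppm1d (0.0307) and Pglyrp1 (0.0465). Ppm1d and Pglyrp1 were above the floor in 0 of 5 infected and 5 of 5 PBS brains, so their values are lower limits to the size of the difference.

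Interferon-stimulated genes did not pass as a group on day 1 (17 tested, 3 higher, median -0.38, camera adjusted p = 0.911). The smallest p among them were those of Ifi204 at -1.57 ± 0.76, Trim21 at -1.09 ± 0.77, Gbp2b at -1.55 ± 1.23 and Usp18 at -1.10 ± 1.01. Endothelial and blood-brain barrier markers (18 tested, 16 lower, median -0.39), lymphocyte and NK markers (18 tested, median -0.44) and choroid plexus markers (11 tested, median -0.64) did not pass either. Inflammatory mediators lay within their errors: S100a8 at 0.64 ± 0.66, Ccl5 at 0.47 ± 0.68, Icam1 at 0.43 ± 0.89, Ccl2 at 0.24 ± 0.99, Il1b at 0.04 ± 0.91, Irf1 at -0.17 ± 1.11 and Cxcl9 at -0.36 ± 1.76. Median, mean and camera direction, which is relative to the other genes, differed in sign for 7 of 22 lists: cytokines (median -0.36, upward), adhesion, immediate early, heat shock and ribosomal genes and astrocyte and oligodendrocyte markers.

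The median of all tested probes was -0.21 on day 1, and 0.09 with scaling over all probes, 0.50 on the deposited scale and 0.06 after quantile normalization. The first principal component (32.3% of the variance) parted infected replicates 4 and 5 and PBS replicates 5 and 1b from the other 6 brains. The respiratory chain list had an adjusted p of 0.0122 with these clusters as a block, 0.000764 within the 4 brains and 0.214 within the 6. It lost its call without PBS replicates 1a (0.796), 3 (0.156) or 4 (0.201) and without infected replicates 3 (0.0634), 4 (0.643) or 5 (0.586), and in the fit as first written (0.879). The call was also lost without both PBS arrays of mouse number 1 (0.403), after quantile normalization (0.213), with a lower floor (0.357), no filter (0.217) or a stricter one (0.0524), with scaling over all probes (0.116) and on the deposited scale (0.222). Without infected replicate 1, 2 lists passed.

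On day 2, B2m, the light chain of MHC class I molecules, and Nudt1, an enzyme that clears oxidised nucleotides, rose in infected brains. B2m (probe H13a5/b5) was higher by 4.56 ± 0.86 (SE, n = 5 and 5, limma adjusted p = 0.0115), with a mean of 4.26 ± 0.40 (SD) against -0.30 ± 1.31 in PBS brains. Nudt1 (probe D01c4/d4) was higher by 6.22 ± 1.12 (adjusted p = 0.0115), with a much wider spread in infected brains (SD 3.60) than in PBS brains (SD 0.54). Probes E09c7/d7 (5.82 ± 1.03, adjusted p = 0.0102) and K06a3/b3 (4.64 ± 0.85, adjusted p = 0.0115) also rose. Each of the 4 was above the PBS mean in 5 of 5 infected brains.

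**Figure D2:**
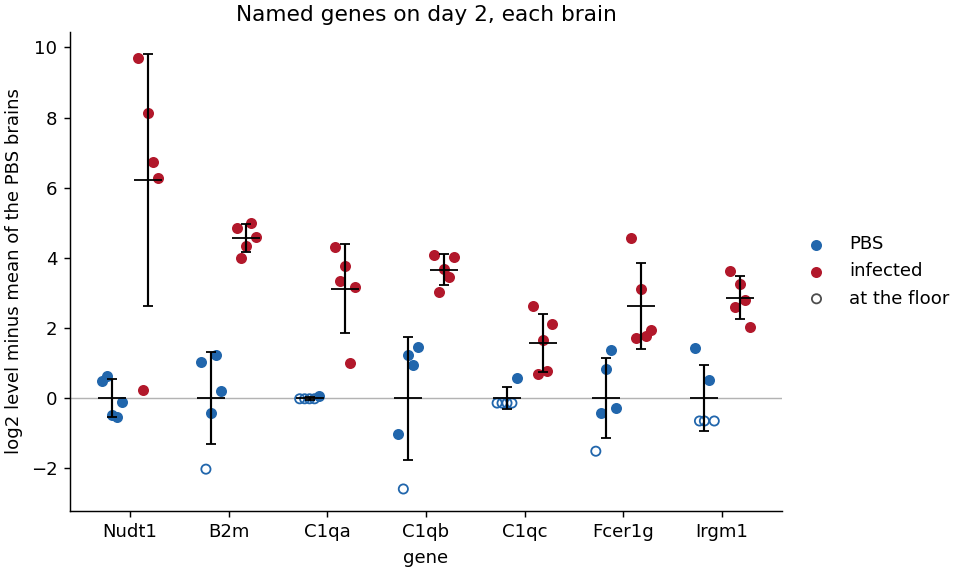
Level of 7 genes in each brain of day 2 (y axis, log2 level minus the PBS mean), PBS in blue, infected in red, open symbols at the floor, bars mean and SD. B2m lay between 4.01 and 5.01 in infected brains and between -2.03 and 1.22 in PBS brains, and Nudt1 between 0.24 and 9.70 in infected brains.

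These were 4 of 2649 probes, all higher, with 77 at an unadjusted p under 0.05 (57 higher, 20 lower). The exact Mann-Whitney test on the deposited scale gave 57 probes at that level and 0 after adjustment, and of 56 with a 2-fold difference 27 were higher and 29 lower. The fit as first written called 0, and none of the 4 was called with scaling over all probes (adjusted p 0.0626 to 0.0799) or on the deposited scale (0.415 to 0.921). With the mouse number as a block 0 probes were called. Called probes numbered 1 with a lower floor, 2 with a stricter filter and 2 with the arrays of the day alone. With array weights they numbered 14, among them C1qa, Gjb6, Pvalb and Irgm1. Gjb6 also passed with no filter (0.0431), without infected replicate 7 and without both arrays of largest scale factor (0.0162). B2m lost its call without PBS replicate 8 (4.06) or infected replicate 11 (4.45), and Nudt1 without infected replicate 9 (5.74), PBS replicate 10 (6.08) or infected replicate 11 (6.09). K06a3/b3 lost it without PBS replicate 8 (4.15) or 10 (4.15) or infected replicate 9 (4.51) or 11 (4.47). The number of probes called was 2, 1, 2 and 2 without PBS 8, infected 11, infected 9 and PBS 10.

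Microglia markers rose as a group on day 2. Of 10 tested, 8 had a higher mean, the median was 1.66, and the camera adjusted p was 5.9e-07 (0.0403 with an estimated correlation). The members of smallest p were C1qa at 3.13 ± 0.79, C1qb at 3.66 ± 1.03 and C1qc at 1.57 ± 0.75, which form the recognition molecule of classical complement, and Fcer1g, a signalling chain of Fc receptors, at 2.62 ± 1.04. None passed over all probes, and 2 passed adjusted over the list alone. C1qa and C1qc were above the floor in 5 of 5 infected and 1 of 5 PBS brains, so their values are lower limits to the size of the difference.

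Complement genes rose as well (7 tested, 5 higher, median 1.57, camera adjusted p = 0.000199, and 0.0403 with an estimated correlation). The list shares the 3 C1q genes with the microglia list, and 2 members passed adjusted over the list alone. The C1q genes had a median of 3.13 and the other 4 tested members of -0.022. Cd59a, an inhibitor of the membrane attack complex, was at 1.64 ± 0.72. Blood leukocyte lists did not pass on day 2: monocyte and macrophage markers had a median of -0.63 (7 tested, adjusted p = 0.83), neutrophil markers of -0.48 (5 tested, 0.980) and lymphocyte and NK markers of 0.04 (10 tested, 0.871).

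Genes of the glucocorticoid response rose on day 2 (11 tested, 9 higher, median 0.76, camera adjusted p = 0.0105). Adjusted p was 0.216 with an estimated correlation. Examples were Gjb6, an astrocyte gap junction protein, at 4.15 ± 1.08, Tsc22d3, a glucocorticoid-induced leucine zipper protein, at 1.87 ± 0.71, Cdkn1a, a cell cycle inhibitor, at 1.52 ± 0.78, and Glul, glutamine synthetase, at 0.87 ± 0.56, and 1 member passed adjusted over the list alone. The call was lost without PBS replicate 8 (0.0762) or infected replicate 11 (0.0510), without both arrays of largest scale factor (0.101), with a lower floor (0.0764) and in the fit as first written (0.287).

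Neuron and synapse markers fell as a group (33 tested, 25 lower, median -0.45, camera adjusted p = 0.0105). Adjusted p was 0.0527 with an estimated correlation. Gabra2 and Gria2, receptor subunits for GABA and glutamate, were at -1.86 ± 0.93 and -0.97 ± 0.66, Gad2, which makes GABA, at -2.55 ± 1.4 (-0.56 without PBS replicate 7), and Pvalb, a calcium-binding protein of interneurons, went the other way at 2.40 ± 0.75. No member passed adjusted over the list alone. Gabra2 was above the floor in 1 of 5 infected and 3 of 5 PBS brains, so the size of its difference depends on the floor. Pvalb was above it in 5 of 5 infected and 1 of 5 PBS brains, so its value is a lower limit. The call was lost without infected replicate 12 (0.0519), with the replicate number as a block and on the deposited scale (0.177).

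Cytokines and chemokines fell as a group (22 tested, 16 lower, median -0.29, camera adjusted p = 0.0362). Adjusted p was 0.140 with an estimated correlation. The T cell attractants Ccl22 and Ccl17 were at -1.44 ± 0.80 and -1.17 ± 0.94, Il1b at -1.13 ± 0.91 and Lta at -1.0 ± 0.83, and 0 members passed adjusted over the list alone. The call was lost without infected replicates 7 (0.0817), 8 (0.0950), 9 (0.0605) or 11 (0.0622) and PBS replicates 8 (0.0574), 9 (0.0527) or 11 (0.114), without both arrays of largest scale factor (0.101), with a lower floor (0.103) or no filter (0.0601), on the deposited scale (0.135) and in the fit as first written (0.212).

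**Figure D3:**
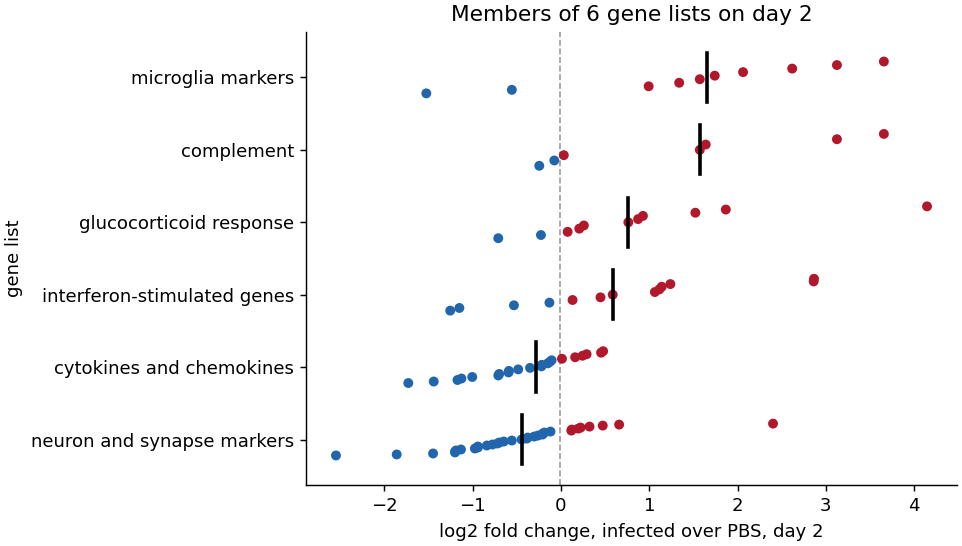
Log2 fold change on day 2 (x axis) of the tested members of 6 gene lists (y axis), with black bars at the list medians. A dashed line marks the median of the other tested genes. Medians were 1.66 for microglia, 1.57 for complement, 0.76 for glucocorticoid response, 0.59 for interferon-stimulated genes, -0.29 for cytokines and chemokines and -0.45 for neuron and synapse markers.

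Interferon-stimulated genes did not pass with camera on day 2 (13 tested, 9 higher, median 0.59, camera adjusted p = 0.0668). Adjusted p was 0.160 with an estimated correlation. In fry the list passed (adjusted p = 0.0124), as did microglia (0.00760), complement (0.00302) and neuron markers (0.00709), while the glucocorticoid and cytokine lists did not (0.138 each). Irgm1, a GTPase of defence against intracellular bacteria, was at 2.86 ± 0.90, above the floor in 5 of 5 infected and 2 of 5 PBS brains. Adar, an RNA-editing enzyme, was at 2.87 ± 1.28 (1.14 without infected replicate 11), with 3 of 5 infected and 1 of 5 PBS brains above the floor. Irf9 was at 1.24 ± 0.61, and Isg15 at 1.11 ± 0.73 with 4 of 5 infected and 0 of 5 PBS brains above the floor. The sizes of the Adar and Isg15 differences therefore depend on the floor, and that of Irgm1 is a lower limit. The list passed in camera with a lower floor (0.00282), with no filter (0.0335), with scaling over all probes (0.0118), on the deposited scale (0.0280) and in the fit as first written (0.0411). MHC genes (11 tested, 6 higher, adjusted p = 0.129, and 0.337 with an estimated correlation) had 1 member, B2m, past the threshold adjusted over the list alone, beside H2-Ab1 at 2.12 ± 1.4, H2-D1 at 1.61 ± 1.10 and H2-Oa at 0.85 ± 0.65. That list passed with a lower floor (0.0480), with no filter (0.0220), without infected replicate 7 (0.0499) and in the fit as first written (0.0163).

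Leukocyte adhesion and migration genes did not pass (10 tested, 7 higher, adjusted p = 0.129, and 0.222 with an estimated correlation), with Madcam1 at 1.89 ± 0.85, Selplg at 1.35 ± 0.73, Itgal at 1.07 ± 0.64 and Sele at 1.30 ± 0.93, and passed with a stricter filter (0.0445). Cxcl9 was at -1.73 ± 1.76, Ccl5 at -0.48 ± 0.68, Icam1 at 0.24 ± 0.89 and Irf1 at -0.13 ± 1.11. Median, mean and camera direction differed in sign for 6 of 21 lists: apoptosis genes (median -0.69, mean 0.07, upward), neutrophil markers (median -0.48, upward), heat shock genes (-0.06, upward), lymphocyte and NK markers (0.04, downward), endothelial markers (0.07, downward) and immediate early genes (median 0.10, mean -0.015, upward). The median of all tested probes was -0.01, and -0.27 with scaling over all probes and -0.31 on the deposited scale.

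On day 3, no gene or list passed in the fit without a block. With the replicate number as a block, which left out infected replicate 18 and PBS replicate 17, 1 list did, ribosomal proteins (camera adjusted p = 0.0130). The smallest p belonged to Ghrhr, the receptor of growth hormone-releasing hormone, at 3.69 ± 0.94 (SE, n = 4 and 4), Il12b, a subunit of interleukin 12, at 4.18 ± 1.13, Fdft1, squalene synthase, at 3.42 ± 1.05, and Tcf21, a transcription factor, at 2.58 ± 0.83. Their limma adjusted p was 0.341, 0.341, 0.402 and 0.402, and each was above the PBS mean in 4 of 4 infected replicates. Il12b was the 1 cytokine past the threshold adjusted over the list alone. limma called 0 of 797 probes, with 39 at an unadjusted p under 0.05 (16 higher, 23 lower), and the exact Mann-Whitney test gave 4 at that level and 0 after adjustment.

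The microglia, complement, glucocorticoid, MHC and leukocyte adhesion lists had under 5 members tested on days 3 and 4, so they could not be tested there. Of the 10 lists tested on day 3, ribosomal proteins had 13 of 17 members lower and a median of -0.78 (camera adjusted p = 0.684). With the replicate number as a block, and so without infected replicate 18 and PBS 17, the adjusted p was 0.0130, and with a stricter filter 0.0326. The block and the omission of these brains were not told apart. Adjusted p was 0.955 with an estimated correlation and no block. In fry no list of day 3 passed, the smallest adjusted p being 0.897. Median, mean and camera direction differed in sign for 2 of 10 lists, cytokine and innate genes, both upward. Interferon-stimulated genes were at a median of -0.12 (6 tested, adjusted p = 0.944), with Ifi47 at -2.31 ± 1.18, Irf1 at 1.58 ± 1.25, Ifi203 at -1.43 ± 1.16 and Gbp2 at 0.87 ± 1.42. Without infected replicate 16, Gbp2 was at 0.027 and Irf1 at 0.75, and Ifi47 was at -1.34 without PBS 12 and 13. Ccl5 was at -1.26 ± 0.76 (-0.49 without PBS 16) and Cxcl9 at -0.58 ± 1.96. The count of probes was 5 without PBS replicates 12 and 13 (Ghrhr among them, at 4.90), 1 without PBS 16 (Il12b, at 5.47) and 1 without PBS 17 (Fdft1, at 4.75), and 1 list passed without infected replicate 18. The median of all tested probes was -0.18, and 0.03 after quantile normalization.

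On day 4, Mt1, a metal-binding metallothionein, and Gpx3, a secreted glutathione peroxidase, passed as higher in infected brains. Of 100 splits of the day 4 arrays, the real one included, 64 called as many probes, so chance cannot be excluded for this count. With the mouse number as a block 0 probes passed. Mt1 (probe K13c7/d7) was higher by 2.52 ± 0.53 (SE, n = 5 and 5, limma adjusted p = 0.0143), with a mean of 2.87 ± 0.60 (SD) against 0.35 ± 1.24 in PBS brains. Gpx3 (probe M04a3/b3) was higher by 2.22 ± 0.48 (adjusted p = 0.0143), with a mean of 2.51 ± 0.55 (SD) against 0.28 ± 0.94. Both were above the PBS mean in 5 of 5 infected brains. Genes that did not pass included Apoe, a lipid carrier, at -3.29 ± 0.88 (adjusted p = 0.131), Cox7a2 at -2.89 ± 0.88, Nefm, a neurofilament protein, at -2.25 ± 0.69, and Ptpn5, a phosphatase of striatal neurons, at -1.94 ± 0.62 (each 0.268). Cox7a2 was above the floor in 0 of 5 infected and 4 of 5 PBS brains, so the size of its difference depends on the floor. With a lower floor Apoe and Cox7a2 passed, each at -4.49 (adjusted p = 0.0480). Without PBS replicate 19, Apoe (-4.16), Cox7a2 (-3.61) and Nefm (-2.82) passed, and without PBS 21 Apoe and Nefm, while without PBS 18 Apoe was at -2.17 and Nefm at -1.43.

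**Figure D4:**
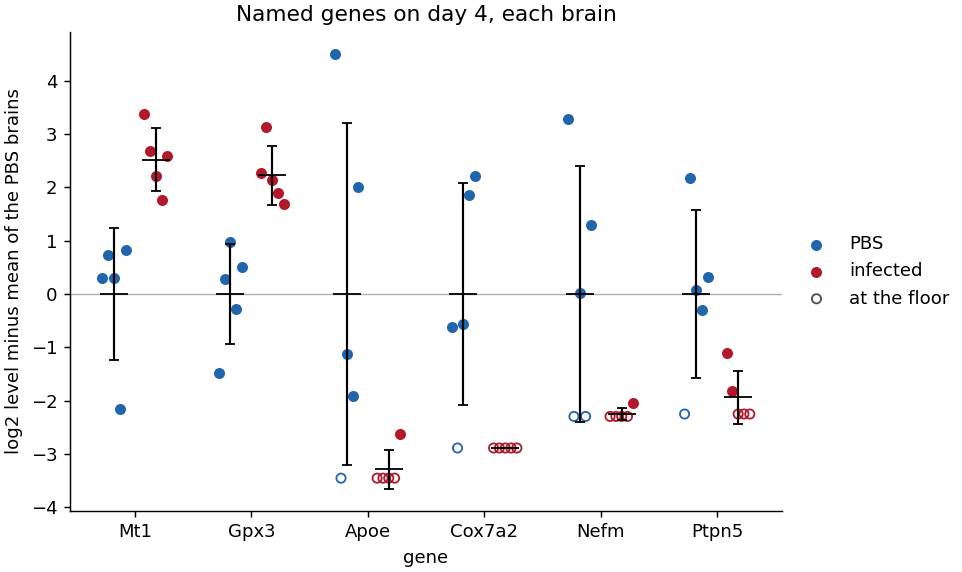
Level of 6 genes in each brain of day 4 (y axis, log2 level minus the PBS mean), PBS in blue, infected in red, open symbols at the floor, bars mean and SD. Mt1 lay between 1.76 and 3.37 and Gpx3 between 1.70 and 3.14 in infected brains, against -2.17 to 0.83 and -1.48 to 0.97 in PBS brains.

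Mt1 and Gpx3 were 2 of 647 probes, with 94 at an unadjusted p under 0.05, of which 9 were higher and 85 lower. The exact Mann-Whitney test gave 28 at that level and 0 after adjustment. The fit as first written called 1 probe, E09c7/d7 at 10.73, and neither gene. Both calls were lost with array weights (adjusted p 0.391 and 0.516), with the arrays of the day alone (0.719 each), with scaling over all probes (0.272 and 0.298) and on the deposited scale (0.808 each), and that of Gpx3 with a lower floor (0.0607). Mt1 lost its call without infected replicate 19 (2.31) or 20 (2.48) or PBS replicate 21 (1.98), and Gpx3 without PBS replicate 18 (1.86) or infected replicate 19 (2.21) or 20 (2.00). The count was 1 without PBS 18, 0 without infected 19, 5 without PBS 19 and 0 without infected 20.

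The median of all tested probes on day 4 was -0.97, and -0.87 with scaling over all probes and on the deposited scale and -0.07 after quantile normalization. None of 8 lists passed, with 0 at an unadjusted camera p under 0.05. The smallest camera adjusted p was 0.377, for innate sensing, ribosomal and respiratory chain genes, and the smallest in fry was 0.498. The microglia, complement and glucocorticoid lists called on day 2 were not among the lists tested, since too few of their members were. Median, mean and camera direction differed in sign for 5 of 8 lists (cytokine, innate, ribosomal and respiratory chain genes and astrocyte markers, all upward relative to the other genes). Adjusted over the list alone, 2 innate genes passed (Mt1, and Rela, a subunit of NF-κB, at -2.49 ± 0.92), and 1 each of the respiratory chain (Cox7a2), astrocyte (Apoe) and neuron lists (Nefm). Neuron and synapse markers had a median of -1.17 (15 tested, 12 lower, adjusted p = 0.678). Interferon-stimulated genes had a median of -1.15 against -0.98 for the others (5 tested, adjusted p = 0.678), with Gbp2 at -2.51 ± 1.27, Ifit1 at -1.44 ± 1.01, Ifi203 at -1.04 ± 1.04 and Gbp2b at -1.15 ± 1.23. Without PBS replicate 18, Gbp2 was at -1.10, Ifit1 at -0.92 and Ifi203 at -0.24. Gbp2b was at -2.71 without infected replicate 22 and at -0.48 without PBS replicate 19. Of the inflammatory genes named regardless of result, only Cxcl9 (0.12 ± 1.76) and Irf1 (0.04 ± 1.11) could be tested.

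Infection effects were then compared between days, and no difference passed in limma. B2m differed between day 2 and day 1 by 4.95 ± 1.12, C1qa by 4.2 ± 1.08, Nudt1 by 5.97 ± 1.56, K06a3/b3 by 4.44 ± 1.16 and Hnrnpc, an RNA-binding protein, by 4.63 ± 1.22 (adjusted p = 0.457 for each). In that contrast 0 of 2429 probes passed and 65 had an unadjusted p under 0.05. Without infected replicate 8 of day 2, 1 probe passed, Nudt1. Between day 3 and day 1 (766 probes, 0 passed, 9 unadjusted, smallest adjusted p 1.00) the smallest p were those of Vdr at -3.84 ± 1.35, Fdft1 at 4.05 ± 1.64, Trim28 at 3.81 ± 1.57, Ghrhr at 3.32 ± 1.37 and Dnajc5 at -3.42 ± 1.43. Between day 4 and day 1 (606 probes, 0 passed, 23 unadjusted, smallest adjusted p 0.998) they were those of Mt1 at 3.15 ± 1.08, Sox13 at -4.31 ± 1.66, Tgfbi at -3.96 ± 1.62, Vegfa at -2.85 ± 1.17 and Srprb at -3.4 ± 1.4. Over all 4 days (430 probes, 0 passed, 10 unadjusted, smallest adjusted p 1.00) the largest F were 5.71 for Srprb, 4.99 for Mt1, 3.94 for Tcf21, 3.39 for Sox13 and 3.26 for Apoe, and 1 probe passed without PBS replicates 12 and 13 of day 3. The days on which a gene passed were therefore not shown to differ from the others in its effect, and for lists this was not tested.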

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

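In the tests reported here, those of the scaling and of the floor and filter for day 4, and those of blood leukocytes, of the 2 arrays with the largest scale factors, of the scaling and of the C1q genes in the complement list for day 2, were chosen only after the result was seen. Of 170 groups of brains tested, 25 had 1 brain far from the others by Dixon's criterion, and chance gives 8.5. In most of them all other brains sat at the floor, where any value above it stands apart.

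On day 1 the log2 scale factor of infected replicate 4 was 3.05, against -0.20 to 0.63 in the other infected arrays, and Usp18 was at 1.96 in infected replicate 3. Among PBS brains of day 2, replicate 7 stood apart with Pvalb at 8.91, Adar at 7.30, Gad2 at 8.86 and Ccl17 at -2.32, replicate 8 with Cd59a at 6.98 and Selplg at -2.32, and replicate 11 with C1qa at 6.36, C1qc at 6.97 and Sele at 8.23. Among infected brains of day 2, replicate 7 had Gjb6 and Icam1 at -2.32, replicate 9 had Gabra2 at -0.18 and replicate 12 had Ccl22 at -0.56. On day 3, infected replicate 15 had Ifi47 at -1.28 and Ifi203 at 1.58, and infected replicate 18 had Ccl5 at 0.49. On day 4, PBS replicate 21 had Mt1 at -1.82, and without it the log2 fold change of Mt1 was 1.98 and no longer past the threshold. Infected replicate 23 had Apoe at -1.50, Nefm at -2.07, Gbp2 at -2.09, Ifit1 at -1.53 and Ifi203 at 1.23, and infected replicate 22 had Gbp2b at 5.48.

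The microglia and complement lists were higher in infected brains on day 2. Blood leukocytes left in the tissue would raise their own markers, but 22 such markers had a median of -0.23 against 1.66 for 10 microglia markers, which argues against that source for the microglia list. With the preset correlation, the tables also argue against the arrays with the largest scale factors as the whole cause. Without them the larger adjusted p of both lists in limma's camera was 0.000718, up to 0.00734 with a further array left out. The tables likewise argue against the C1q genes as the whole cause for the microglia list (camera p 0.00218, unadjusted, over the remaining markers, up to 0.0194). An estimated correlation, which gave an adjusted p of 0.0403 for each whole list, was not tried in these tests. On the deposited scale the larger camera adjusted p was 6.57e-05, up to 0.00327. Camera compares a list with the other genes, so a shift shared by all genes largely cancels, and that value cannot decide about the scaling. The complement call may rest on the C1q genes alone, since the remaining complement genes had a median of -0.022 against 3.13 for C1q, with a camera p of 0.399 (0.136 to 0.799 with an array left out). For the microglia list a candidate explanation is a response of microglia to the infection, found and tested on the same data. A larger number of microglia or other macrophages was not tested against higher expression per cell. A floor and filter tied to the PBS median was not tested as a cause for either list, though both passed with each other floor and filter tried. C1qa and C1qc, above the floor in 5 of 5 infected and 1 of 5 PBS brains, met the filter through the infected brains.

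The median of all tested probes on day 4 lay at -0.97, and 1 of 126 splits of the arrays, the real one, gave a median as far from 0 (highest other 0.911). The division by the PBS median, the floor and the filter follow the real groups and were not redone for other splits. That count therefore does not by itself exclude chance. The median was -0.57 with the number of detected probes as a covariate (-0.65 to -0.23 with 1 array left out), -0.60 without PBS replicate 18 (-0.74 to -0.43) and -0.87 on the deposited scale (-0.99 to -0.50), and the ranges reach past the limit of -0.50 set for them, so none of these is excluded. Over the 69 probes detected on every array, the median on the deposited scale was 0.18 (0.06 to 0.56). All 69 passed the filter, but their values were also floored at 0.2 of the PBS median. That median is therefore not free of the floor and cannot decide the question. Over all tested probes the median was -0.25 with no filter, -0.32 with a stricter one, -0.48 with a higher floor and -1.21 with a lower one. A floor and filter tied to the PBS median could therefore contribute and is left open, since simulated arrays with no changed probe gave a median of only -0.30 (-0.52 to -0.11) at the wider spread. A fall of many transcripts in infected brains stays open and untested.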

How the results depend on the processing

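Alternatives chosen after seeing the data were the scalings, the variance trend on scaled levels, the fit as first written and the array clusters. So were leaving out the 2 arrays of largest scale factor and, for lists, the stricter filter and the doubtful labels. The planned pooling of PBS arrays, cyclic loess and the test among PBS groups were not run, and the planned dim filter removed no probe. Of 2572 values of genes and lists under alternatives, 2366 kept direction and side of the threshold, 75 turned sign, 99 were no longer past it and 32 newly past. Turned signs included 0 called genes or lists. The microglia and complement lists passed with each of 10 replicates left out (3.6e-08 to 0.000123 and 4.85e-05 to 0.00183) and under 12 of 12 other alternatives, up to 0.0403. The neuron list passed under 9 of 10 and 9 of 12, glucocorticoid 8 of 10 and 7 of 12, cytokines 3 of 10 and 5 of 12, and the respiratory chain of day 1 4 of 10 and 5 of 15. B2m passed under 8 of 10 and 7 of 14, Nudt1 7 and 4, E09c7/d7 10 and 10, K06a3/b3 6 and 5, Mt1 7 and 8, and Gpx3 7 and 7. The cause was not tested for any change between settings given here. Signal near the floor limits days 3 and 4 most, with 190 and 69 probes detected on every array.

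Quantile normalization gave 0 lists on day 1, Cxcl9 at 0.0053 on day 1 and Ifi203 at 0.29 on day 4. A floor at 0.25 of the one used gave 1 probe on day 2, 4 on day 4 (1 higher, Mt1, and 3 lower, Apoe, Cox7a2 and Tsnax), 0 lists on day 1, Cxcl9 at -0.051 on day 4 and an interferon list p of 0.891 on day 1. A floor 2.5 times higher gave 1 probe for day 2 against day 1 (B2m), Irf1 at 0.24 on day 1, Icam1 at -0.022 on day 2 and an interferon p of 0.755 on day 3. Without a filter, 8 probes passed on day 1, all lower, with 0 lists, and the interferon p of day 3 was 0.995. A stricter filter gave 2 probes on day 2, 0 lists on day 1 and 1 list on day 3. The median of all tested probes on day 4 was -1.21 with the lower floor, -0.48 with the higher one, -0.25 without a filter and -0.32 with the stricter one. Array weights gave 14 probes on day 2, 4 of them shared, 0 on day 4, and Cxcl9 at 0.039 on day 1. Without the doubtful labels there were 1 probe and 3 lists on day 2, 0 lists on day 1, Irf1 at 0.020 on day 2 and an interferon p of 0.957 on day 3.

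With the replicate block, 0 probes passed on days 2 and 4 and 1 list on day 3, Irf1 was at 0.16 on day 1 and 0.20 on day 2, Icam1 at -0.39 on day 2, and the interferon p was 0.638 on day 3 and 0.966 on day 4. The fits with the block also left out brains whose number occurs in only 1 group. The numbers were not taken to pair samples on days 1, 2 and 4, where not every sample correlated best with its own number. Correlations were 0.41, -0.38, 0.04, -0.08 and 0.33 on day 1, 0.14, 0.18, 0.01 and 0.08 on day 2, and -0.07, 0.09, -0.10 and -0.07 on day 4. Only the arrays of the day gave 2 probes on day 2 and 0 on day 4. An estimated correlation gave 0 lists on day 1 and 2 on day 2.

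Scaling over all probes gave 0 probes on days 2 and 4, 0 lists on day 1, and Cxcl9 at 0.052 and Irf1 at 0.23 on day 1. The deposited scale gave the same counts of 0, Cxcl9 at 0.64 and Irf1 at 0.83 on day 1, and H2-Oa at -0.14 and Icam1 at -1.01 on day 2. The fit as first written gave 0 probes on day 2, 1 on day 4, 0 lists on day 1, Cxcl9 at 0.052 and Irf1 at 0.32 on day 1, and interferon p of 0.923 on day 1 and 0.897 on day 3. Within the upper cluster of day 1, 1 probe (lower) and 2 lists passed, with Ccl2 at -2.23, Cxcl9 at 1.09, Irf1 at 0.99 and Il1b at -1.35, and within the lower one 0 lists. Without the 2 arrays of largest scale factor, 2 probes (E09c7/d7 and Gjb6) and 3 lists passed on day 2, and Irf1 was at 0.41. The Mann-Whitney test gave 207, 57, 4 and 28 probes on days 1 to 4, 159, 56, 3 and 28 with a 2-fold difference, and 0 after adjustment. The number of replicates nearly fixed that last count.

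Of 77 named fold changes, 43 moved by over 1.5 times or turned in sign without some 1 replicate, among them 0 called genes. Those not given elsewhere ranged, on day 1, Ccl5 0.22 to 0.69, S100a8 0.22 to 0.82 and Usp18 -1.96 to -0.56, on day 2, Ccl17 -1.77 to -0.87, Cxcl9 -2.54 to -0.62, Gabra2 -2.43 to -1.15, H2-D1 1.04 to 2.33, H2-Oa 0.55 to 1.13, Il1b -1.51 to -0.42, Isg15 0.63 to 1.39, Itgal 0.63 to 1.29, Lta -1.67 to -0.58, Sele 0.63 to 1.73 and Selplg 0.65 to 1.62, with H2-Ab1 as low as 1.47, and on day 3, Fdft1 2.18 to 4.75 and Ifi203 -2.41 to -0.90, with Tcf21 as low as 1.52. With 1 replicate left out, probes numbered 0 to 0 on day 1, 1 to 5 on day 2, 0 to 5 on day 3 and 0 to 5 on day 4, and lists 0 to 2, 3 to 5 (3 without PBS 8 or infected 11), 0 to 1 and 0 to 0. Contrasts gave 0 to 1 over all days and for day 2 against day 1, and 0 to 0 otherwise. The interferon p ranged from 0.606 to 0.983 on day 3 and 0.318 to 0.926 on day 4. Ranges that crossed 0 were, on day 1, Ccl2 -0.33 to 0.87, Cxcl9 -0.94 to 0.14, Icam1 -0.030 to 0.66, Il1b -0.47 to 0.80 and Irf1 -0.87 to 0.39. On day 2 they were Icam1 -0.32 to 0.87 and Irf1 -0.89 to 0.26, on day 3 Cxcl9 -1.90 to 0.13, and on day 4 Cxcl9 -0.99 to 1.78 and Irf1 -0.61 to 1.01.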

Other observations

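In the tests reported here, those of the floor and filter and of the splits with the mouse number as a block were chosen only after the result was seen. Beyond the lists described, Serpina3n, an acute phase protease inhibitor made by reactive astrocytes, was at 2.99 ± 0.86 on day 2 and Birc5, an inhibitor of apoptosis in dividing cells, at 2.65 ± 0.85. Each passed adjusted over the list alone, as 1 of 21 innate sensing genes and 1 of 11 apoptosis genes, and neither passed over all probes except with array weights (3.06 and 2.64). Astrocyte markers had 1 such member, Gjb6, and a median of 0.22 (14 tested, adjusted p = 0.269). Oligodendrocyte markers were at a median of -0.27 (11 tested, adjusted p = 0.770) and endothelial markers at 0.07 (10 tested, 0.980). Probe E09c7/d7 had a mean of 5.89 with an SD of 0.10 over the 5 infected brains of day 2, against an SD of 2.18 in PBS brains.

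The explanation of the day 4 shift by a floor and a filter was tested in 3 ways in turn, with its prediction rewritten each time. The median over the 26 tested probes with a recovered lowest level was 0.47, against -1.03 over the 621 others. That comparison went with the explanation and was dropped as void, since the limit of 0.01 and the division by the PBS median largely decide which probes are recovered. Simulated unchanged arrays gave medians of -0.01 (-0.04 to 0.04) with the same share of undetected values on every array, -0.15 (-0.22 to -0.10) with the real shares, and -0.01 (-0.15 to 0.12) and -0.30 (-0.52 to -0.11) with a wider spread. The median of 0.18 over the 69 probes detected on every array was computed last, after the simulated values were seen. Those probes were floored at 0.2 of the PBS median too, so it leaves the explanation open.

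Other splits of the arrays were fitted in the same way. On day 2, 1 of 100 splits, the real one, gave as many probes (4, highest other 2) and 1 of 100 as many lists (5, highest other 3). Those shares lie under 0.05. They do not by themselves exclude chance, since the division by the PBS median, the floor and the filter favour no split but the real one. On day 4, 64 of 100 splits gave as many probes as the real 2 (highest other 42, with 54 splits above the real count), and on day 1, 51 of 100 gave as many lists as the real 1 (highest other 5). Chance cannot be excluded for these, and splits that call many more probes than the real one point to a structure of the samples other than infection. Where the real count was 0, every split gives as many, so the comparison says nothing about chance. This holds for the probes of day 1 (100 of 100, highest other 405) and day 3 (35 of 35, highest other 20), the lists of day 3 (35 of 35, highest other 2) and day 4 (100 of 100, highest other 2), and the contrasts between days (100 of 100, highest other 55 over all days and 8, 10 and 22 for days 2, 3 and 4 against day 1). The highest other split of day 1 had 9 of 10 arrays on the side of their cluster on the first principal component. With the mouse number as a block on day 3, 2 of the 4 splits that part each of 3 pairs gave as many lists as the real 1 (highest other 1), and 4 splits are too few for a share under 0.05. The division by the PBS median, the floor and the filter follow the real groups and were not redone for other splits, a limit on all these counts.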
